A study of Homo sapiens with 42 samples.

How the data were processed

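RNA was measured in 42 cultures of human cells, 1 Affymetrix HG-U133 Plus 2.0 array per culture, in 14 groups of 3 biological replicates. The groups were the fibroblast line BJ and its transformed derivative BJ LTSTERas, each untreated at 0 h or treated for 4, 12 or 24 h with DMSO, the solvent, or with vorinostat at 25 µM. Per the submitters' protocol, poly-A control transcripts were added to each RNA sample before labelling. The deposited values were log2 signals per probe set. They were taken here to be made with GCRMA, a background correction by probe sequence with quantile normalization and a summary per probe set. The submitters' processing notes name GCRMA and limma and give no version or role for either.

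The deposited table held 54675 probe sets, 62 of them array controls. Values ran from 0.762 to 16.21, array medians from 2.859 to 2.964, and no normalization was added. Probe sets were named from the annotation supplied with the platform. Of 42898 with a listed gene, 41097 had 1 symbol and 1801 had several, and 11721 had none. The latter 2 kinds were not analysed here, so genes such as BBC3, which had no probe set with 1 symbol, have no value. Probe sets with a log2 signal of at least 4 in at least 3 of the 42 arrays were kept, which left 21127 with 1 symbol. Of the 11412 genes these measure, 5624 had several probe sets, and the probe set with the highest mean over all arrays stood for the gene.

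A linear model with 1 mean per group was fitted to all 42 arrays with limma 3.58.1 in R 4.3.3, with moderated variances and 28 residual degrees of freedom per gene before moderation. Errors given with log2 differences are standard errors (SE) of this fit with 3 arrays per group, and errors of group levels are standard deviations (SD, n = 3). Benjamini-Hochberg adjustment was made within each comparison, and genes with an adjusted p under 0.05 were called. All tests were 2-sided. The comparisons were vorinostat against DMSO of the same time in each line, the difference of that effect between lines at each time, the change of the effect from 4 h to 24 h in each line, untreated BJ LTSTERas against untreated BJ, and DMSO against untreated cells.

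Gene lists were tested with camera, which asks whether the genes of a list differ from the other genes, at its preset correlation of 0.01. The same test with the correlation estimated for each list was an alternative, and so was fry, a rotation test that asks whether a list's genes move, on balance, 1 way and compares them with no other genes. List tests were adjusted by Benjamini-Hochberg within 3 families, of 222 tests for vorinostat against DMSO, 111 for the differences between lines and 37 for the untreated lines. Of 39 lists with 706 genes, 539 genes were measured and 37 lists had the 3 measured members needed for a test. The lists were written from textbook knowledge, not chosen on these samples, and counts of called list members are also given with the adjustment over the list alone.

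The groups, comparisons, thresholds, lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. Named genes were the 5 largest rises and 5 largest falls past the threshold in each vorinostat comparison whose arrays did not overlap between groups, with the higher group mean at log2 6 or more. For the difference between lines the same number was taken with the highest of the 4 means at log2 6 or more, and for the untreated lines 10 in each direction. Up to 4 members with the largest change past the threshold were taken from each list described, and BCL2 family genes, CDKN1A, TXNIP, HRAS and TERT always. Of 6 arrays, 3 of each group, chance alone keeps 10% of genes free of overlap. The form of the rule was extended to the change from 4 h to 24 h and to DMSO against untreated cells after the data were seen. The list and comparison pairs described, and any other gene with values in the text, were likewise picked after their values were seen.

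The model was tested on simulated data, in which 200 genes were shifted by a log2 of 0.5, 1 or 2 in the BJ LTSTERas 24 h vorinostat arrays. At a shift of 1, 70.1% of shifted genes were called for vorinostat in BJ LTSTERas at 24 h and 59.7% for the difference between lines, and of the genes called there 8.28% and 5.93% were not shifted. With 3 arrays per group, the number of arrays limits the precision of every value. Group means near log2 2 to 3.5 were read as background. Background differs by probe set and can lie higher, as with TERT, flat at 5.33 to 5.48 in all 14 groups. A log2 difference that starts or ends at background is a difference from background.

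Alternatives changed 1 choice at a time, and a range of adjusted p over the alternatives leaves out the estimated correlation and fry for lists. They were no filter or a floor of log2 6, the mean of a gene's probe sets, no probe sets with an ID ending in _x_at, a second quantile normalization, centring of each array on its median, a 2-fold minimum, moderation with a trend, array weights, the replicate number as a block, a fit of only the groups compared, untreated arrays as control, leaving out 3 BJ LTSTERas arrays described as a second scan, and leaving out each array in turn. Same-numbered replicates were read as deviating together where r across genes was over 0.1 for all 3 numbers. This held in 20 of 20 pairs of groups within a line (0.339 to 0.799) and in 0 of 13 across lines, where r was 0.13 to 0.404 for numbers 1 and 2 and -0.196 to 0.0325 for number 3. After this was seen, a block by replicate number within each line, camera with its correlation estimated under that block, and a fit without the 7 BJ replicate 1 arrays were added. The untreated lines share no such block, so that block gives their comparison no value. Tables and figures were made with the R package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.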

Results

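Gene expression was measured in a pair of related human cell lines exposed to vorinostat, an inhibitor of histone deacetylases, enzymes that remove acetyl groups from histones and other proteins. BJ cells are normal foreskin fibroblasts. BJ LTSTERas cells are their tumorigenic derivative, which carries the SV40 large T and small t antigens, the catalytic subunit of telomerase and an oncogenic form of HRAS. The series title places the work among studies of histone deacetylase inhibitors that bring about pro-apoptotic responses selective for tumor cells. Each line was sampled untreated at 0 h and after 4, 12 and 24 h with DMSO or with 25 µM vorinostat, with 3 arrays in each of the 14 groups. Array medians lay between log2 2.859 and 2.964, and replicates of a group had Pearson's r across probe sets of 0.975 to 0.996. In all 7 BJ groups replicate 1 stood apart, with an SD of the difference of 0.405 to 0.586 from replicates 2 and 3, which differed by 0.251 to 0.293. The line separated arrays along the first principal component, which held 44.6% of the variance, and vorinostat and its duration along the second, which held 32.2%.

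**Figure D1:**
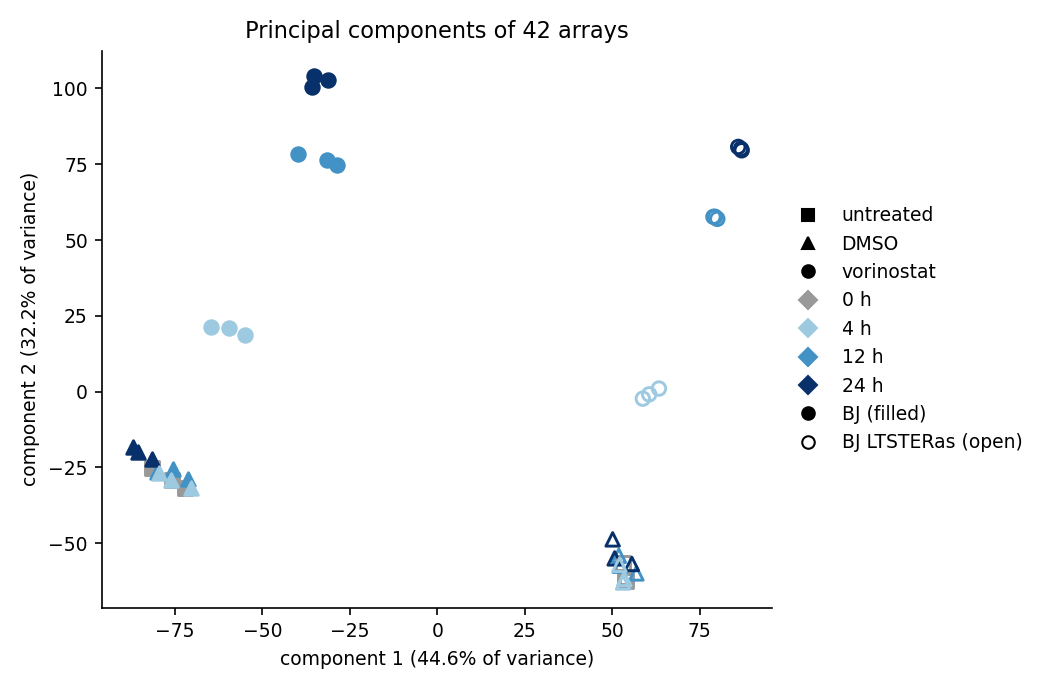
Each point is 1 of the 42 arrays, placed by its scores (arbitrary units) on the first principal component (44.6% of the variance, horizontal axis) and the second (32.2%, vertical axis) of 11412 genes, with shape for treatment, colour for time, and filled points for BJ and open ones for BJ LTSTERas. BJ arrays lie between -87.1 and -28.7 on the first and BJ LTSTERas arrays between 50.2 and 87.1, while on the second DMSO and untreated arrays lie at -62.9 to -18.2 and vorinostat arrays at 24 h at 79.6 to 104.

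The untreated lines were compared to describe the transformed state before treatment. Fibroblast genes were far lower in BJ LTSTERas. COL3A1 (probe set 215076_s_at), which encodes the chain of type III collagen, stood at log2 3.42 ± 0.15 (SD, n = 3) against 15.07 ± 0.08 in BJ, with a difference of -11.65 ± 0.14 (limma adjusted p = 1.22e-34). The cadherin CDH11 (-11.02 ± 0.08), IGFBP5 (-10.84 ± 0.16), the small proteoglycan LUM (-10.70 ± 0.33) and the desmosomal protein DSP (-9.78 ± 0.29) followed. Next came the sulfatase SULF1 (-9.44 ± 0.26), the chemokine CXCL12 (-9.42 ± 0.44), the matrix protein FBLN1 (-9.15 ± 0.34), the retinaldehyde dehydrogenase ALDH1A1 (-9.03 ± 0.30) and ARMCX2 (-8.83 ± 0.20). Highest over BJ was G0S2 (213524_s_at), a regulator of lipolysis, at 12.77 against 4.83, a difference of 7.94 ± 0.45 (adjusted p = 5.99e-16). CLDN11 (7.76 ± 0.46), DNER (7.61 ± 0.17), the angiotensin receptor AGTR1 (7.07 ± 0.48), and LPAR3 (7.03 ± 0.25) were next, then BCHE (6.66 ± 0.32), the chemokine CXCL5 (6.65 ± 0.50), CLGN (6.59 ± 0.20), DOCK4 (6.32 ± 0.37) and TRPA1 (6.30 ± 0.20).

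By list, all 14 measured fibroblast genes were lower in BJ LTSTERas, with a median of -5.0 (camera adjusted p = 2.67e-13). PDGFRA measured -8.58 ± 0.22 and DCN -8.44 ± 0.29. Of 26 extracellular matrix genes 25 were lower and 0 higher (26 lower when adjusted over the list alone; median -2.84, adjusted p = 1.56e-20). Among 19 myofibroblast genes 15 were lower and 1 higher (median -2.46, adjusted p = 2.04e-08). The contractile proteins TAGLN (-7.92 ± 0.41), ACTA2 (-5.69 ± 0.54) and CNN1 (-4.08 ± 0.31) were among them. These 3 calls held with an estimated correlation, at adjusted p = 6.7e-07, 0.0122 and 4.67e-04. The matrix proteases and their inhibitors were lower for 11 of 13 and higher for 2 (median -1.57, adjusted p = 8.32e-04, and 0.24 with an estimated correlation). MMP2 measured -4.42 ± 0.28 and PLAU, the urokinase activator of plasminogen, at 2.34 ± 0.27. Targets of p53, the tumor suppressor that large T antigen binds, were lower for 13 of 18 and higher for 0 (13 lower and 1 higher adjusted over the list alone; median -1.58, adjusted p = 8.01e-07, and 0.0207 with an estimated correlation). GDF15 measured -4.81 ± 0.56, ZMAT3 at -3.25 ± 0.22 and the cell cycle inhibitor CDKN1A at -3.21 ± 0.26. Of 26 replication genes 21 were higher and 1 lower (22 and 1 adjusted over the list alone), with a median of 1.22 (adjusted p = 6.64e-06, and 0.323 with an estimated correlation). ORC1 (2.11 ± 0.26) and PRIM1 (1.78 ± 0.22) led it. Mitosis genes were higher for 25 of 30 and lower for 0 (28 higher adjusted over the list alone), with a median of 1.42 (adjusted p = 1.53e-04, and 0.599 with an estimated correlation). The kinase AURKA measured 2.01 ± 0.31. Genes of double-strand break repair were higher for 20 of 25 and lower for 0 (21 higher adjusted over the list alone; median 0.86, adjusted p = 1.83e-04, and 0.291 with an estimated correlation). BRCA1 measured 1.56 ± 0.26 and RAD51C at 1.47 ± 0.16. Ribosome biogenesis genes were higher for 17 of 18, with a median of 0.94 (adjusted p = 7.07e-07, and 0.0966 with an estimated correlation). UTP20 measured 1.55 ± 0.19. In all, limma called 3269 genes higher and 2806 lower, 53.2% of those tested. HRAS, which was placed in the cells on a vector, differed by 0.84 (adjusted p = 0.135, 0.0208 with array weights and 0.0221 with the block by replicate number, in a range of 0.0208 to 0.497 over the alternatives). The probe set of TERT, also placed on a vector, stood at 5.33 to 5.48 in all 14 groups and gave no measure of it.

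Vorinostat changed a large share of measured genes in both lines, and the number grew with time. At 4, 12 and 24 h in BJ, 1712, 3074 and 3470 genes rose and 1844, 3122 and 3468 fell. These were 31.2%, 54.3% and 60.8% of the genes tested. In BJ LTSTERas 1824, 3450 and 3878 genes rose and 2266, 2930 and 3317 fell, or 35.8%, 55.9% and 63.0%. Centring each array on its median shifted the median of all genes by at most 0.12 on the log2 scale, in BJ at 24 h, but moved the share of rises among called genes by up to 6.98 points. It went from 48.1% to 53.4% and from 49.6% to 56.3% in BJ at 4 and 12 h, from 44.6% to 50.8% in BJ LTSTERas at 4 h, and for the difference between lines from 57.1% to 50.4% at 12 h and from 56.7% to 50.8% at 24 h.

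**Figure D2:**
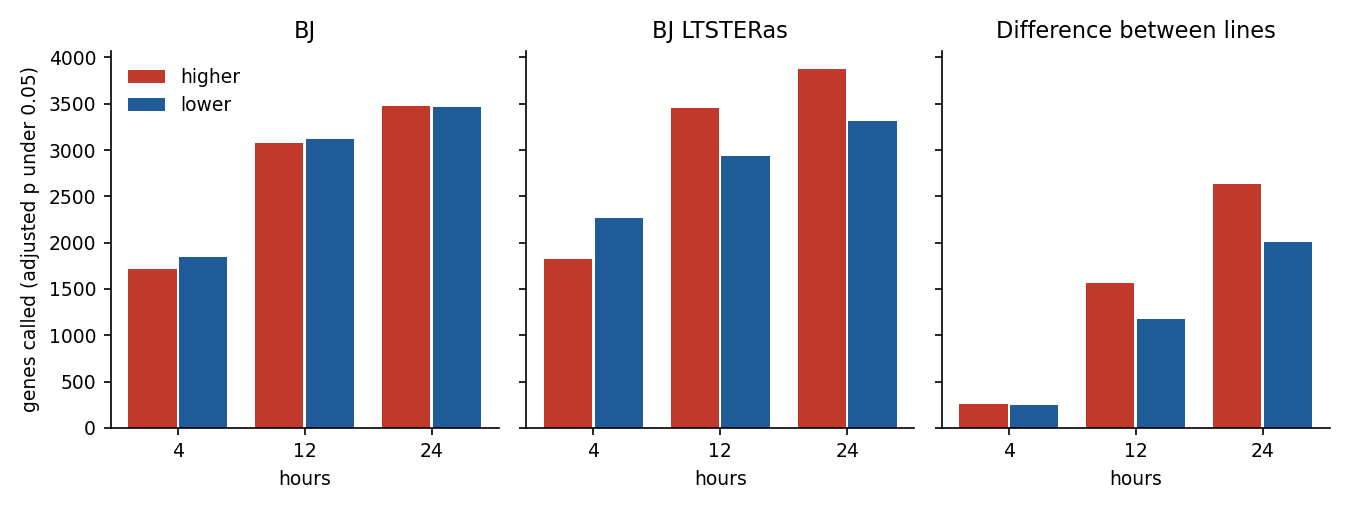
Bars give the numbers of higher and lower genes with an adjusted p under 0.05 (vertical axis) at 4, 12 and 24 h (horizontal axis). They cover vorinostat against DMSO in BJ, in BJ LTSTERas, and the difference of the effect between lines, with 3 arrays per group. In BJ the rises go from 1712 at 4 h to 3470 at 24 h, in BJ LTSTERas from 1824 to 3878, and genes with a greater value in BJ LTSTERas go from 259 to 2630.

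In BJ at 4 h PTGER4, a receptor for prostaglandin E2, rose by 6.41 ± 0.22 (adjusted p = 1.39e-20), followed by the granzyme inhibitor SERPINB9 (6.16 ± 0.31), the transcription factor GRHL1 (6.03 ± 0.10), the tubulin TUBB2B (5.73 ± 0.30) and the virus receptor and adhesion protein CXADR (5.26 ± 0.29). HAS2 (230372_at), a hyaluronan synthase, fell from 11.51 to 3.85, a log2 change of -7.66 ± 0.47 (adjusted p = 2.47e-14), ahead of PHETA2 (-4.77 ± 0.15), the chromatin protein HMGA2 (-4.68 ± 0.42), SALL1 (-4.61 ± 0.29) and HOXB2 (-4.35 ± 0.23). Histone acetyltransferases and bromodomain readers, proteins that write and read the acetyl marks, fell for 8 of 14 and rose for 0 (median -0.45, adjusted p = 0.0107, and 0.488 with an estimated correlation). KAT6B (-2.55 ± 0.21), EP300 (-2.05 ± 0.25) and CREBBP (-1.51 ± 0.14) were among them. That call ended in a fit of only the groups compared (adjusted p = 0.146) and without _x_at probe sets (0.0554), with a range of 8e-05 to 0.146 over the alternatives. Of 8 inhibitors of the step from G1 to S phase 2 rose and 1 fell (adjusted p = 0.734). CDKN2B measured 3.17 ± 0.32 and CDKN1B at -1.22 ± 0.18. The immediate early genes FOS (2.73 ± 0.49) and DUSP5 (3.12 ± 0.23) rose and FOSL1 (-3.02 ± 0.47) fell.

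At 12 h in BJ the hormone gene SST (213921_at) rose by 8.01 ± 0.17, TUBB2B by 7.56 ± 0.30, CXADR by 7.02 ± 0.29, TMEFF2 by 7.02 ± 0.24 and the actin bundler PLS1 by 6.39 ± 0.33. The homeobox genes LHX9 (-7.28 ± 0.35) and MKX (-6.66 ± 0.25), HMGA2 (-7.25 ± 0.42), PLAU (-6.58 ± 0.27) and the actin-binding NEXN (-6.27 ± 0.18) fell furthest. Neuronal and synaptic genes rose for 9 of 16 and fell for 0 (median 0.82, adjusted p = 0.00212, and 0.0328 with an estimated correlation). The neurofilament genes INA (5.97 ± 0.32) and NEFH (4.19 ± 0.10) were among them. All 8 metallothioneins, small proteins that bind metals, rose (median 1.05, adjusted p = 0.00365, and 0.501 with an estimated correlation), MT1E by 1.59 ± 0.12. Replication genes fell for 19 of 26 and rose for 0 (21 fell adjusted over the list alone; median -0.98, adjusted p = 2.21e-04, and 0.507 with an estimated correlation). GINS3 measured -3.49 ± 0.19 and POLE2 at -2.91 ± 0.20. G1/S cyclins and E2F targets fell for 14 of 23 and rose for 1 (15 and 2 adjusted over the list alone; median -0.93, adjusted p = 0.0012, and 0.501 with an estimated correlation). UHRF1 measured -2.56 ± 0.12. Mitosis genes fell for 25 of 30 and rose for 0 (26 fell adjusted over the list alone; median -1.30, adjusted p = 9.19e-04, and 0.751 with an estimated correlation). PLK1 measured -3.20 ± 0.80. This list's adjusted p was 0.155 with untreated arrays as control (range 3.3e-07 to 0.155). The p53 targets fell for 12 of 18 and rose for 1 (13 and 1 adjusted over the list alone; median -0.89, adjusted p = 0.0127, and 0.501 with an estimated correlation). TP53I3 measured -2.29 ± 0.21 and MDM2 at -1.95 ± 0.15.

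At 24 h in BJ every measured mitosis gene had fallen, and SST and the chemokine CXCL8 stood at high levels. SST rose from 2.35 ± 0.01 (SD, n = 3) to 12.10 ± 0.16, by 9.75 ± 0.17 (adjusted p = 1.41e-29). The neutrophil chemokine CXCL8 (202859_x_at) rose from 3.15 ± 0.57 to 10.90 ± 0.44, by 7.75 ± 0.53 against DMSO (adjusted p = 4.78e-14), where untreated BJ stood at 8.82 and DMSO had fallen from it by 5.67. ENPP5 (7.56 ± 0.07), DNER (7.46 ± 0.17) and PLS1 (7.28 ± 0.33) were next. The mitotic kinesin KIF20A (218755_at) fell from 11.20 ± 0.07 to 2.87 ± 0.46, a log2 change of -8.34 ± 0.55 (adjusted p = 2.29e-14). The mesenchymal homeobox gene PRRX1 (-8.16 ± 0.36), the deiodinase DIO2 (-7.87 ± 0.54), the interferon-inducible TRIM22 (-7.84 ± 0.32) and the decoy receptor TNFRSF11B (-7.73 ± 0.17) followed. All 30 mitosis genes fell, with a median of -4.70 (adjusted p = 7.02e-14, and 0.501 with an estimated correlation). CDC20 (-7.56 ± 0.50), KIF2C (-7.26 ± 0.33) and DLGAP5 (-7.06 ± 0.41) fell with KIF20A. Replication genes fell for 22 of 26 and rose for 1 (23 and 1 adjusted over the list alone; median -1.28, adjusted p = 5.71e-06, and 0.501 with an estimated correlation). MCM10 measured -4.20 ± 0.22 and CDC45 at -3.64 ± 0.18. G1/S cyclins and E2F targets fell for 16 of 23 and rose for 2 (the same counts adjusted over the list alone; median -1.48, adjusted p = 2.4e-04, and 0.501 with an estimated correlation). TYMS measured -4.82 ± 0.25.

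Rising lists in BJ at 24 h included neuronal and synaptic genes, 12 up and 2 down of 16 (median 1.76, adjusted p = 7.96e-04, and 0.0226 with an estimated correlation). The list was led by SCG2 (7.19 ± 0.23), INA (6.89 ± 0.32), NEFH (6.04 ± 0.10) and SNAP25 (4.10 ± 0.27). Estimated under the block by replicate number within a line, that p was 0.186. All 8 metallothioneins rose (median 2.14, adjusted p = 3.04e-05, and 0.488 with an estimated correlation), MT1M by 6.15 ± 0.15. MT1M was not read from an _x_at probe set, unlike MT1E, MT1F, MT1G, MT1H and MT1X. Replication-dependent and linker histone genes rose for 8 of 10 and fell for 0 (median 2.29, adjusted p = 0.00653, and 0.501 with an estimated correlation). H2BC21 measured 4.07 ± 0.28 and H2AC8 at 3.81 ± 0.26. Here and below this list reads polyadenylated transcripts, not total histone mRNA. Cholesterol synthesis genes rose for 9 of 13 and fell for 0 (10 rose adjusted over the list alone; median 0.87, adjusted p = 0.0267, and 0.488 with an estimated correlation). INSIG1 measured 4.43 ± 0.39 and DHCR7 at 1.97 ± 0.33. The cholesterol list's adjusted p was 0.459 with untreated arrays as control and 0.0795 without _x_at probe sets (range 0.00134 to 0.459). The senescence-associated secretory list rose for 9 of 22 and fell for 5 (median 0.17, adjusted p = 0.237). Its largest rises were of the chemokines CXCL8, CCL20 (7.14 ± 0.16), CXCL2 (4.14 ± 0.44) and CXCL3 (3.88 ± 0.32). Against untreated BJ arrays these 4 measured 2.08, 7.11, 2.11 and 3.26. IL6 and CXCL1, at 1.57 and 3.48 against DMSO, measured -0.29 and -0.18 against untreated arrays. The p53 targets fell for 11 of 18 and rose for 1 (the same counts adjusted over the list alone; median -0.91, adjusted p = 0.0302, and 0.501 with an estimated correlation). That call ended with untreated arrays as control (adjusted p = 0.107) and without BJ vorinostat 24 h replicate 1 (0.0539), in a range of 0.00274 to 0.107.

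In BJ LTSTERas at 4 h GRHL1 led the rises, at 5.84 ± 0.10 (adjusted p = 4.17e-29), with LMCD1 (5.09 ± 0.16), CRISPLD2 (5.08 ± 0.38), the Notch target HEY1 (5.06 ± 0.26) and PLPPR4 (4.92 ± 0.31). HAS2 fell by 6.56 ± 0.47 on the log2 scale (adjusted p = 7.11e-13), ahead of a polyadenylated transcript listed under MIR34A (235571_at; -4.58 ± 0.29), which is not a measure of the microRNA, the Wnt antagonist DKK1 (-4.24 ± 0.12), METTL18 (-4.18 ± 0.26) and the cytokine IL6 (205207_at; -4.10 ± 0.54). Acetyltransferases and bromodomain readers fell for 7 of 14 and rose for 0 (median -0.57, adjusted p = 0.00212, and 0.488 with an estimated correlation). KAT6B measured -3.37 ± 0.21 and EP300 at -1.86 ± 0.25. Cholesterol synthesis genes rose for 8 of 13 and fell for 0 (median 0.81, adjusted p = 0.019, and 0.488 with an estimated correlation). INSIG1 rose by 2.03 ± 0.39 and HMGCS1 by 1.14 ± 0.27. Without _x_at probe sets that list's adjusted p was 0.0686, and 0.0513 with untreated arrays as control (range 0.0016 to 0.0686). Among 8 inhibitors of G1/S kinases 3 rose and 3 fell (median -0.01, mean 0.62, camera upward with adjusted p = 0.627), with CDKN2B at 4.40 ± 0.32, CDKN2D at 2.06 ± 0.38, CDKN1A at 1.38 ± 0.26 and CDKN1B at -1.53 ± 0.18.

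At 12 h in BJ LTSTERas CRISPLD2 (7.25 ± 0.38), TUBB2B (6.50 ± 0.30), the GABA transaminase ABAT (6.46 ± 0.21), the neuronal microtubule protein MAP2 (6.15 ± 0.38) and C7orf57 (6.01 ± 0.22) rose most. PLAU (-8.14 ± 0.27), NAV3 (-7.41 ± 0.34), the coreceptor NRP1 (-7.17 ± 0.25), EVI2A (-6.93 ± 0.39) and HMGA2 (-6.80 ± 0.42) fell most. Genes of RAS-MAPK output and feedback fell for 14 of 27 and rose for 6 (median -0.81, adjusted p = 0.0174, and 0.515 with an estimated correlation). FOSL1 measured -5.19 ± 0.47 and the cyclin gene CCND1 at -4.98 ± 0.27. FOS rose by 4.33 ± 0.49.

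At 24 h in BJ LTSTERas NRP1 (212298_at), a coreceptor for semaphorins and growth factors, fell from 11.59 ± 0.05 (SD, n = 3) to 2.14 ± 0.05, a log2 change of -9.46 ± 0.25 (adjusted p = 1.13e-24). Then came PLAU (205479_s_at; -9.11 ± 0.27), HMGA2 (-8.54 ± 0.42), the collagen chaperone SERPINH1 (-8.32 ± 0.21) and NAV3 (-7.67 ± 0.34). The dehydrogenase DHRS2 (206463_s_at) rose from 3.15 ± 0.01 to 10.67 ± 0.33, by 7.52 ± 0.17 (adjusted p = 2.11e-26), and so did CCL20 (7.43 ± 0.16), C7orf57 (6.90 ± 0.22), ABAT (6.83 ± 0.21) and MAP2 (6.69 ± 0.38). Extracellular matrix genes fell for 14 of 26 and rose for 3 (median -1.34, adjusted p = 0.0012, and 0.562 with an estimated correlation). The crosslinking enzymes LOXL1 (-5.33 ± 0.24) and LOX (-5.14 ± 0.23) fell and LUM rose by 3.77 ± 0.33. Matrix proteases and inhibitors fell for 9 of 13 and rose for 1 (median -1.09, adjusted p = 0.0225, and 0.507 with an estimated correlation). MMP2 measured -2.54 ± 0.28 and MMP14 at -2.47 ± 0.22. Histone genes rose for 9 of 10 and fell for 0 (median 2.11, adjusted p = 0.00238, and 0.501 with an estimated correlation). H2AC8 measured 3.51 ± 0.26 and H1-2 at 2.79 ± 0.25. Thioredoxin and NRF2 targets rose for 11 of 15 and fell for 3 (median 1.26, adjusted p = 0.0488, and 0.488 with an estimated correlation). GCLC measured 3.54 ± 0.16, HMOX1 at 3.41 ± 0.39 and the cystine transporter SLC7A11 at -4.40 ± 0.41. The list's call ended without BJ LTSTERas vorinostat 24 h replicate 3 (adjusted p = 0.0559) and under 7 other alternatives, up to 0.077 with untreated arrays as control (range 0.00737 to 0.077). Mitosis genes fell for 14 of 30 and rose for 0 (median -0.59, adjusted p = 0.0979). The list was called in a fit of only the groups compared (0.00141) and with no filter (0.00737), in a range of 0.00141 to 0.125. AURKA measured -2.16 ± 0.31 and CCNB1 at -1.70 ± 0.43. In the secretory list 11 of 22 fell and 3 rose (median -0.67, adjusted p = 0.207, and 0.0405 with no filter, in a range of 0.0405 to 0.274). IL1B measured -7.61 ± 0.64 and IL6 at -5.71 ± 0.54.

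The difference of the vorinostat effect between lines, BJ LTSTERas minus BJ, bears on the selectivity named in the title. At 4 h it passed for 259 genes with a greater value in BJ LTSTERas and 242 with a greater value in BJ. The numbers were 1562 and 1175 at 12 h and 2630 and 2008 at 24 h. With the block by replicate number within a line these counts were 628 and 767 at 4 h and 2789 and 2059 at 12 h. At 4 h PHETA2 (4.77 ± 0.21, adjusted p = 4.82e-17), the protocadherin PCDH10 (4.70 ± 0.51), ST8SIA4 (4.54 ± 0.30), SALL1 (4.54 ± 0.41) and the potassium channel KCNJ2 (4.49 ± 0.30) had the most positive differences. ADAMTS15 (-5.25 ± 0.29, adjusted p = 2.99e-14), the phosphatase DUSP2 (-4.02 ± 0.37), INA (-3.84 ± 0.46) and the chemokines CXCL3 (-3.72 ± 0.45) and CXCL2 (-3.68 ± 0.63) had the most negative. At 12 h LHX9 (7.28 ± 0.49), MKX (6.67 ± 0.35), IRAG1 (6.36 ± 0.29), EFS (6.19 ± 0.34) and DIO2 (5.90 ± 0.76) stood at the positive end. SST (-8.01 ± 0.24), CXCL8 (-6.86 ± 0.75), INA (-5.90 ± 0.46), ENPP5 (-5.82 ± 0.10) and DOCK4 (-5.80 ± 0.53) stood at the negative end. With untreated arrays as control CXCL8 at 12 h measured -1.65 (adjusted p = 0.0995; range 2.51e-12 to 0.0995). The p53 targets separated the lines from 4 h on, with 5 of 18 differences positive and 0 negative (9 and 1 adjusted over the list alone; median 0.55, adjusted p = 5.96e-04, and 0.303 with an estimated correlation). At 12 h 11 were positive and 0 negative (the same counts adjusted over the list alone; median 1.08, adjusted p = 1.84e-05, and 0.116 with an estimated correlation). Metallothioneins at 12 h had 5 negative differences of 8 and 0 positive (median -0.78, adjusted p = 0.00136, and 0.608 with an estimated correlation). Ribosome biogenesis genes had 1 negative difference of 18 at 4 h (2 adjusted over the list alone; median -0.34, adjusted p = 0.00136) and 6 at 12 h (9 adjusted over the list alone; median -0.38, adjusted p = 0.00772), both at 0.608 with an estimated correlation.

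At 24 h DIO2 (7.88 ± 0.76), the transporter SLC38A11 (7.38 ± 0.48), TRIM22 (7.35 ± 0.45), LHX9 (7.35 ± 0.49) and IRAG1 (7.27 ± 0.29) had the most positive differences. CXCL8 (-9.97 ± 0.75, adjusted p = 2.14e-12), SST (-9.75 ± 0.24, adjusted p = 3.82e-25), ENPP5 (-7.55 ± 0.10), IL6 (-7.27 ± 0.76) and CXCL2 (-7.24 ± 0.63) had the most negative. With untreated arrays as control CXCL8 measured -4.53, IL6 -6.23 and CXCL2 -5.98 (adjusted p = 1.14e-05, 6.1e-08 and 3.06e-09, with highest values over the alternatives of 1.14e-05, 1.78e-06 and 1.25e-06). CCL20 rose in both lines and its difference was 0.29 (adjusted p = 0.307). Of 30 mitosis genes 26 had a positive difference, having fallen less in BJ LTSTERas, and 0 a negative one (28 positive adjusted over the list alone; median 3.54, adjusted p = 1.52e-13, and 0.608 with an estimated correlation). KIF20A measured 7.01 ± 0.78 (adjusted p = 1.15e-08) and KIF2C at 6.97 ± 0.47. Replication genes had 16 positive and 1 negative of 26 (18 and 1 adjusted over the list alone; median 1.12, adjusted p = 2.2e-05, and 0.608 with an estimated correlation). MCM10 measured 4.67 ± 0.31. G1/S cyclins and E2F targets had 13 positive and 2 negative of 23 (the same counts adjusted over the list alone; median 0.83, adjusted p = 0.00709, and 0.608 with an estimated correlation).

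Greater values in BJ at 24 h were found for metallothioneins, 7 of 8 (median -1.39, adjusted p = 2.29e-05, and 0.354 with an estimated correlation). MT1M measured -6.14 ± 0.21. Neuronal and synaptic genes had 8 negative and 4 positive differences of 16 (9 and 4 adjusted over the list alone; median -1.20, adjusted p = 0.00167, and 0.0393 with an estimated correlation). INA measured -6.83 ± 0.46 and NEFH at -5.96 ± 0.14. Estimated under the block by replicate number within a line, that p was 0.126. The secretory list had 10 negative and 3 positive of 22 (the same counts adjusted over the list alone; median -1.05, adjusted p = 0.00772, and 0.608 with an estimated correlation). RAS-MAPK output and feedback had 15 negative and 6 positive of 27 (15 and 8 adjusted over the list alone; median -1.15, adjusted p = 0.00772, and 0.608 with an estimated correlation). EMP1 measured -4.76 ± 0.21 and CCND1 at -3.63 ± 0.38. Both calls ended with untreated arrays as control, at adjusted p = 0.113 and 0.544, the highest of ranges that began at 1.55e-04 and 5.3e-05. Extracellular matrix genes had 13 negative and 5 positive of 26 (median -0.88, adjusted p = 0.00438, and 0.678 with an estimated correlation). LOX measured -3.23 ± 0.32 and LUM at 4.20 ± 0.46. The adjusted p was 0.132 with the mean of each gene's probe sets (range 2.4e-05 to 0.132).

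**Figure D3:**
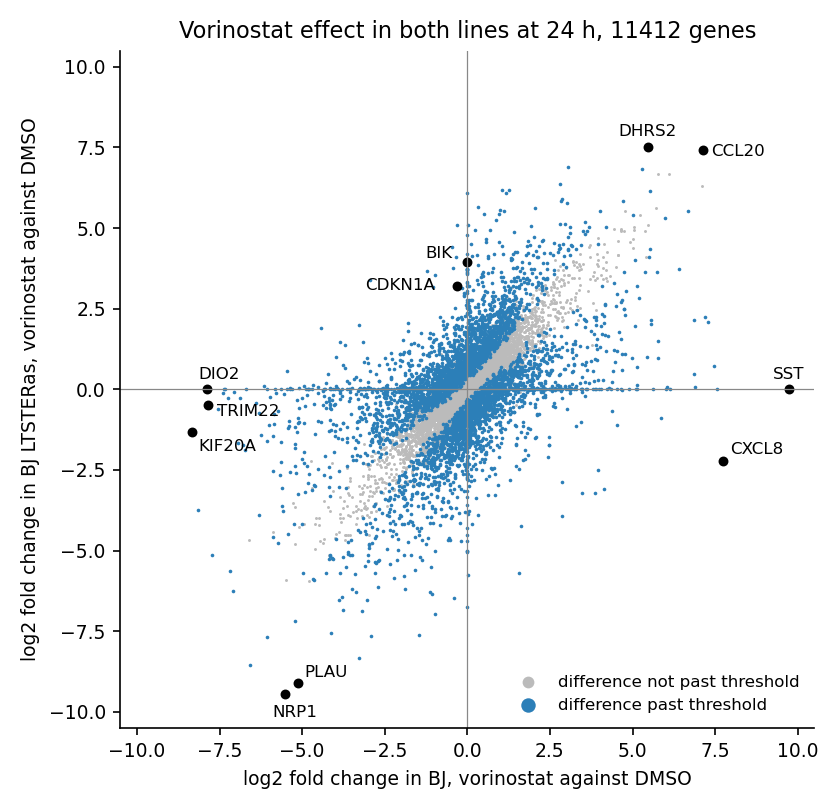
Each point is 1 of 11412 genes, placed by its log2 fold change for vorinostat against DMSO at 24 h in BJ (horizontal axis) and in BJ LTSTERas (vertical axis), coloured where the difference between lines had an adjusted p under 0.05, with 3 arrays per group. SST lies at 9.75 in BJ, KIF20A at -8.34 in BJ, and NRP1 at -9.46 in BJ LTSTERas.

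**Figure D4:**
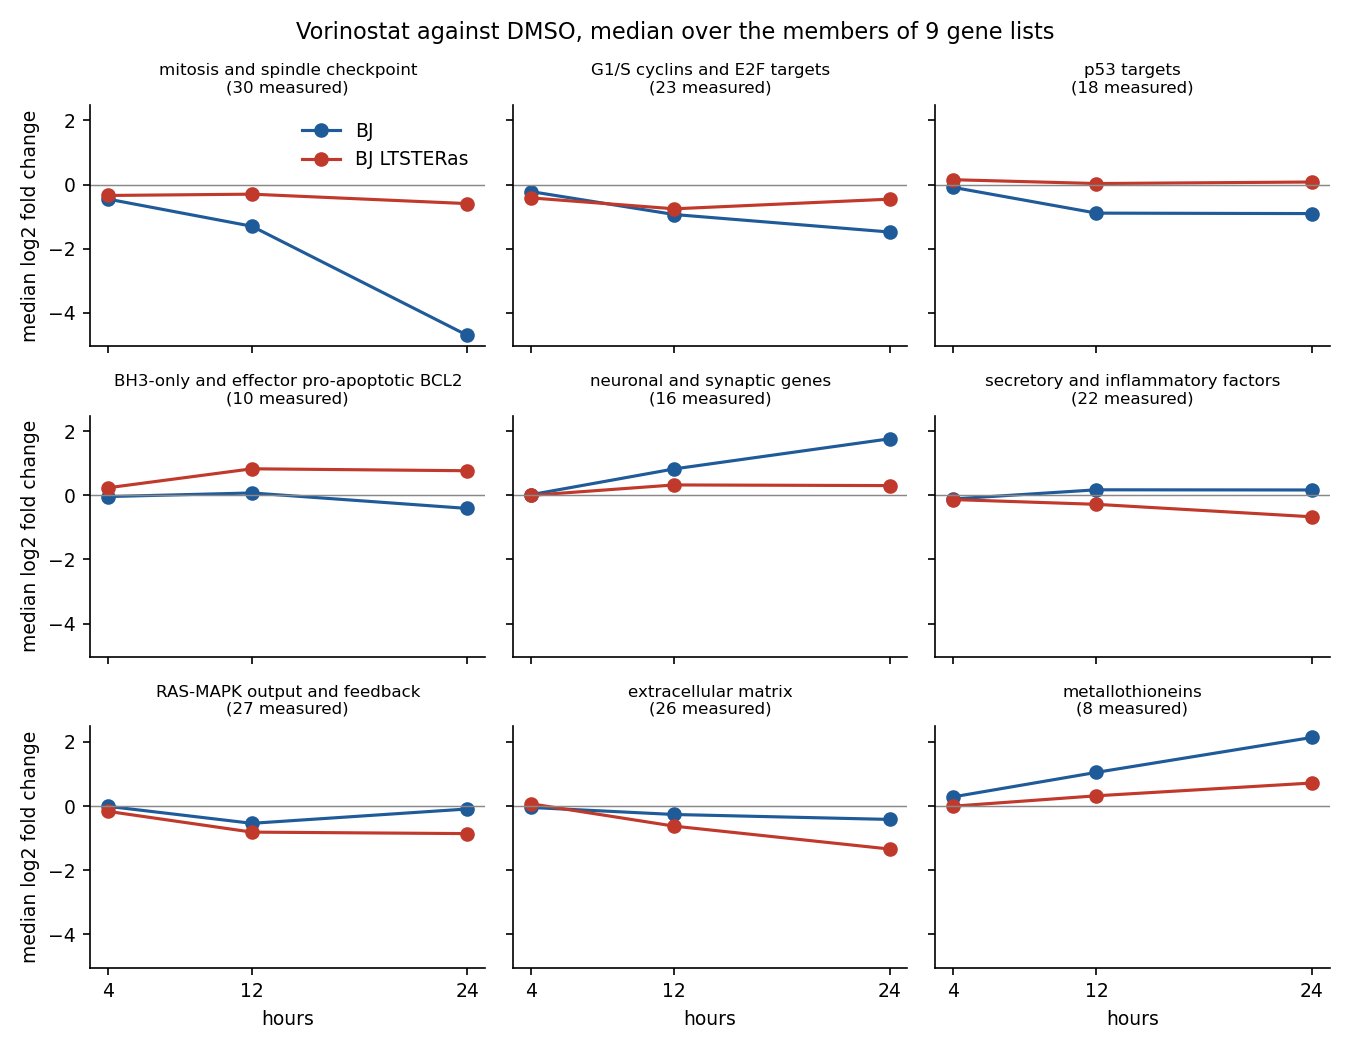
Lines give the median log2 fold change for vorinostat against DMSO (vertical axis) over the measured members of 9 gene lists at 4, 12 and 24 h (horizontal axis) in BJ (blue) and in BJ LTSTERas (red), with 3 arrays per group. The mitosis list reaches -4.70 in BJ and -0.59 in BJ LTSTERas at 24 h, and the metallothioneins 2.14 and 0.72.

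Genes of the BCL2 family set the threshold of mitochondrial apoptosis. At 24 h the difference between lines passed for 5 of 10 pro-apoptotic and 2 of 5 anti-apoptotic members. Of the latter, the BCL2L1 call (1.23, adjusted p = 0.0241) ended with the mean of its probe sets (1.06, 0.347) and without BJ vorinostat 24 h replicate 1, BJ DMSO replicate 2 or 3, BJ LTSTERas vorinostat replicate 2 or BJ LTSTERas DMSO replicate 3 (0.0537 to 0.0911), in a range of 1.23e-05 to 0.347. BIK (205780_at), a pro-apoptotic BH3-only gene, rose in BJ LTSTERas from 2.51 to 6.45 ± 0.16 (SD, n = 3) at 24 h, by 3.95 (adjusted p = 3.5e-19), after 1.26 at 12 h. In BJ it measured 0.03 at 12 h and -0.01 at 24 h. The difference at 24 h was 3.95 ± 0.24 (adjusted p = 1.5e-14). BCL2L11 (1553096_s_at), which encodes the BH3-only protein BIM, rose in BJ LTSTERas by 0.85, 0.92 and 1.66 at 4, 12 and 24 h (SE 0.16; adjusted p = 8.9e-05, 1.4e-05 and 1.7e-10), reaching 7.42 ± 0.34. Untreated and DMSO groups of both lines stood at a flat 5.73 to 5.82, read as background, so these are differences from background. In BJ it measured 0.22, 0.12 and -0.01. Of its other probe sets, 2 rose in BJ by 4.00 and 3.45 at 24 h. With the mean of its probe sets BJ rose by 2.12, 1.67 and 1.49 (adjusted p = 1.61e-15, 9.13e-14 and 8.9e-13, the lowest of ranges up to 0.79, 0.869 and 0.992), and the 24 h difference was 1.78. So whether BCL2L11 rose in BJ depended on the probe set. Its difference was 0.63 (adjusted p = 0.14, and 0.0255 with the block by replicate number within a line, in a range of 0.00805 to 0.53) at 4 h, 0.80 (adjusted p = 0.01) at 12 h and 1.67 (adjusted p = 5.6e-07) at 24 h. A fit of only the groups compared ended its call in BJ LTSTERas at 4 h (adjusted p = 0.0594). The 12 h difference was lost without the second-scan arrays (0.67, adjusted p = 0.0676) and without the 7 BJ replicate 1 arrays (0.74, adjusted p = 0.0565). Over the alternatives these p ranged from 1.08e-17 to 0.0594 and from 9.86e-07 to 0.0676. BAK1, an effector of the mitochondrial pore, rose by 0.78 in BJ LTSTERas at 24 h (adjusted p = 2.3e-04) and measured -0.31 in BJ (adjusted p = 0.12), with a difference of 1.09 (adjusted p = 5.8e-04). BNIP3 rose by 1.33 in BJ LTSTERas and measured -0.51 in BJ, and its difference was 1.84 (adjusted p = 3.5e-07). BAX, another effector, fell by 2.61 ± 0.60 on the log2 scale in BJ (adjusted p = 3.7e-04) and measured -0.76 in BJ LTSTERas (adjusted p = 0.29, and 0.00431 with the block within a line, in a range of 0.00431 to 0.55), with a difference of 1.85 (adjusted p = 0.0833, and 2.09e-05 with the block by replicate number within a line, in a range of 2.09e-05 to 0.325 over the alternatives). BOK, a further effector, fell in both lines at 24 h, with -1.29 in BJ (adjusted p = 0.0019) and -2.27 in BJ LTSTERas (adjusted p = 1.19e-06). Its difference was -0.97 (adjusted p = 0.119), which passed with the block within a line (0.0407) and without BJ LTSTERas vorinostat 24 h replicate 2 (-1.52, 0.00738), in a range of 0.00738 to 0.567. BNIP3L measured 0.44 in BJ LTSTERas (adjusted p = 0.0455) and -0.13 in BJ, with a difference of 0.58 (adjusted p = 0.092, and 0.00617 with the block within a line, in a range of 3.97e-04 to 0.196). The BNIP3L call ended without BJ LTSTERas vorinostat 24 h replicate 1 (0.0989), 2 (0.0517) or 3 (0.107) or DMSO 24 h replicate 1 (0.0719) or 2 (0.163), in a range of 6.46e-04 to 0.163. BAD fell in BJ by 1.5 on the log2 scale, and its difference was 2.25 ± 0.45 (adjusted p = 1.6e-04). BID fell in both lines at 24 h, with -2.58 in BJ and -2.21 in BJ LTSTERas. PMAIP1, which encodes NOXA, rose at 4, 12 and 24 h in BJ LTSTERas by 1.65, 0.72 and 1.45. In BJ it rose by 1.68 at 4 h and 1.81 at 24 h against DMSO, but against untreated arrays it measured 0.47 at 4 h and -0.68 at 24 h (adjusted p = 0.0181 and 3.24e-04, each the highest over its alternatives).

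Of 10 measured pro-apoptotic members, 7 rose and 2 fell in BJ LTSTERas at 24 h (the same counts adjusted over the list alone; median 0.77, adjusted p = 0.316), and 1 rose and 5 fell in BJ (adjusted p = 0.348). The difference between lines was positive for 5 and negative for 0 (the same counts adjusted over the list alone; median 1.38, adjusted p = 0.0232, and 0.471 with an estimated correlation). Without BJ vorinostat 24 h replicate 1 that list measured 1.12 (adjusted p = 0.0503; range 6.07e-04 to 0.0503). Anti-apoptotic members fell for 2 of 5 and rose for 1 in BJ (median 0.00, mean -0.51, camera downward with adjusted p = 0.691) and fell for 3 and rose for 0 in BJ LTSTERas (adjusted p = 0.255). Their difference was positive for 1 and negative for 1 (median -0.01, mean -0.75, adjusted p = 0.366). BCL2A1 (205681_at) fell in BJ LTSTERas from 7.30 to 2.61, a log2 change of -4.69 ± 0.18 (adjusted p = 1.2e-20), and measured 0.00 in BJ, where it was at background. Its difference was -4.69, and untreated BJ LTSTERas exceeded untreated BJ by 6.14. BCL2L1 (212312_at), which encodes BCL-XL, fell in both lines, with -1.91 at 12 h and -2.10 at 24 h in BJ and -1.63 and -0.87 in BJ LTSTERas. The last call (adjusted p = 0.0155) ended without the second-scan arrays (0.0509), BJ LTSTERas vorinostat 24 h replicate 1 (0.0511) or DMSO 24 h replicate 1 (0.0791) or 2 (0.0614), in a range of 6.21e-06 to 0.0791. BCL2 measured 0.45 in BJ at 24 h (adjusted p = 0.0311) and 0.00 in BJ LTSTERas, with a difference of -0.45 (adjusted p = 0.159). Its call in BJ ended with untreated arrays as control (0.11, adjusted p = 0.622) and without BJ vorinostat 24 h replicate 2 (0.142) or DMSO 24 h replicate 1 (0.326), in a range of 0.00825 to 0.622. BCL2L2 fell in both lines at 24 h, with -1.13 in BJ and -0.96 in BJ LTSTERas. MCL1 measured 0.21 in BJ LTSTERas at 24 h (adjusted p = 0.171, and 0.024 with the block within a line, in a range of 0.00266 to 0.629). BMF, HRK, BCL2L14 and BCL2L10 stayed below the signal floor, with highest arrays at 3.32, 2.74, 3.18 and 2.81.

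**Figure D5:**
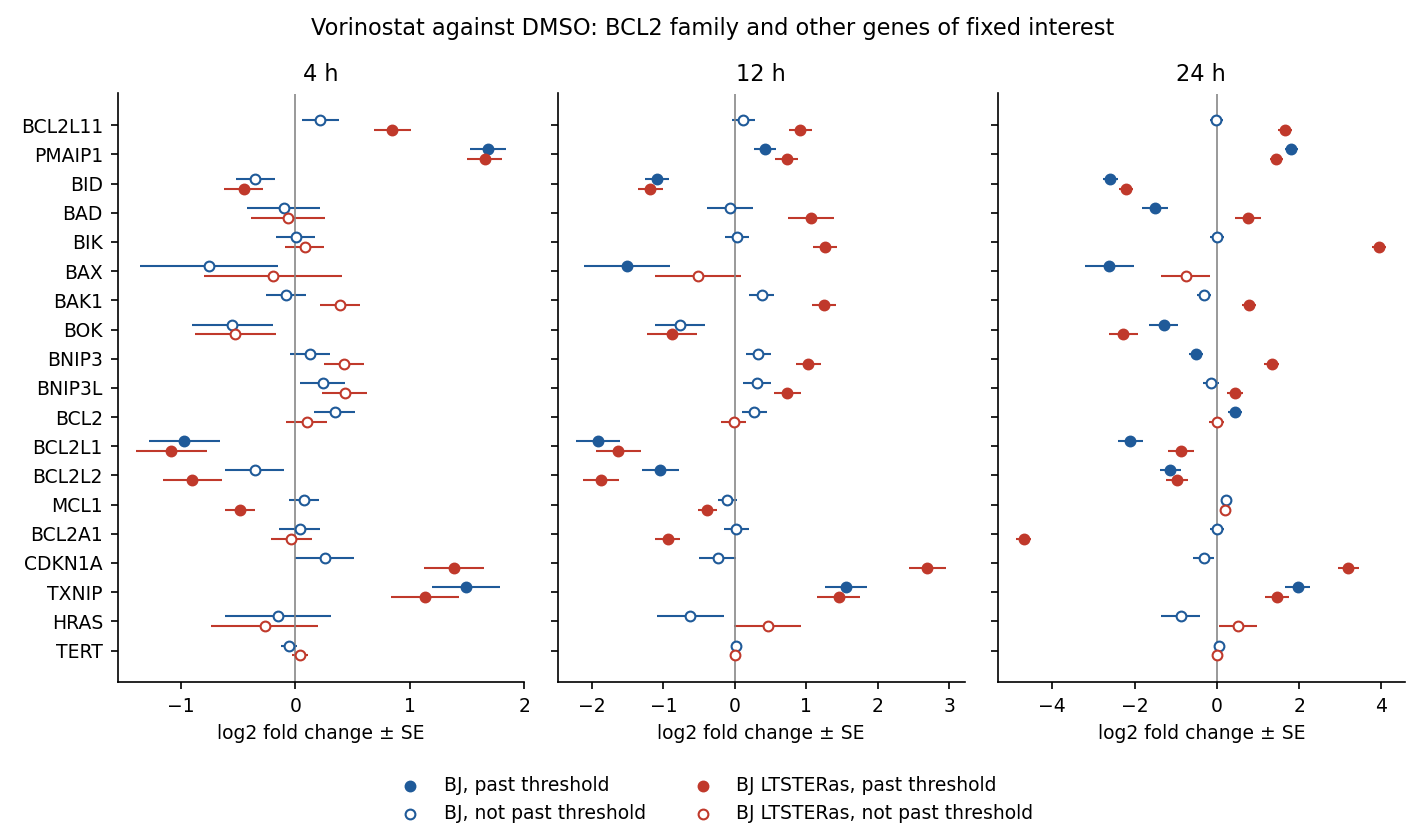
Points give the log2 fold change for vorinostat against DMSO (horizontal axis, scaled per panel) with its standard error, 3 arrays per group, at 4, 12 and 24 h (panels) for BCL2 family genes, CDKN1A, TXNIP, HRAS and TERT (vertical axis) in BJ (blue) and BJ LTSTERas (red), filled where the adjusted p was under 0.05. At 24 h BIK stands at 3.95 in BJ LTSTERas and -0.01 in BJ, and CDKN1A at 3.20 and -0.32.

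Downstream of these genes, genes of the caspase and apoptosome list rose for 6 of 11 and fell for 1 in BJ LTSTERas at 24 h (adjusted p = 0.0798, and 0.0487 without BJ LTSTERas DMSO 24 h replicate 1, in a range of 0.0144 to 0.11 over the alternatives). The initiator caspase gene CASP9 rose by 1.89 ± 0.12, the IAP antagonists DIABLO by 1.75 ± 0.10 and HTRA2 by 1.66 ± 0.17, and cytochrome c (CYCS) by 1.12 ± 0.09. In BJ 4 rose and 3 fell (median 0.30, mean -0.04, camera upward with adjusted p = 0.692). Their difference was positive for 6 and negative for 0 (7 positive adjusted over the list alone; median 0.93, adjusted p = 0.0226, and 0.608 with an estimated correlation), with APAF1, the apoptosome scaffold, at 1.33 ± 0.29 and ENDOG at 1.86 ± 0.28. Death receptor genes fell for 7 of 13 and rose for 2 in BJ (adjusted p = 0.209) and fell for 6 and rose for 1 in BJ LTSTERas (adjusted p = 0.0689, and 0.0439 without BJ LTSTERas DMSO 24 h replicate 1, in a range of 0.0103 to 0.136 over the alternatives). FAS (-4.61 ± 0.41 in BJ, -2.99 ± 0.41 in BJ LTSTERas), CASP8 (-3.75 ± 0.32 and -5.21 ± 0.32) and its inhibitor CFLAR (-3.90 ± 0.21 and -4.42 ± 0.21) fell in both lines. The difference passed for 4 of the 13, 1 positive and 3 negative (adjusted p = 0.31). Among 6 IAP family genes, which restrain caspases, 3 fell and 2 rose in BJ (adjusted p = 0.328), with BIRC5, also a mitotic gene, at -6.88 ± 0.42 and XIAP at -1.95 ± 0.14. In BJ LTSTERas 1 fell and 1 rose (adjusted p = 0.678). XIAP measured -1.24 ± 0.14.

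CDKN1A (202284_s_at), which encodes p21, rose in BJ LTSTERas at each time, by 1.38, 2.70 and 3.20, and measured 0.26, -0.24 and -0.32 in BJ, the last called with the block within a line (adjusted p = 0.0179, in a range to 0.547). Its level at 24 h went from 8.41 ± 0.53 (SD, n = 3) to 11.61 ± 0.33 in BJ LTSTERas and from 11.76 ± 0.20 to 11.44 ± 0.12 in BJ. The difference was 2.94 ± 0.37 (adjusted p = 2.92e-07) at 12 h and 3.52 ± 0.37 (adjusted p = 3.17e-09) at 24 h. The p53 targets as a list rose for 8 of 18 and fell for 2 in BJ LTSTERas at 24 h (the same counts adjusted over the list alone; median 0.08, adjusted p = 0.392). PPM1D measured 1.95 ± 0.12 and SESN1 at 1.60 ± 0.19 up and TP53I3 down at -2.10 ± 0.21. Their difference at 24 h was positive for 11 and negative for 0 (14 positive adjusted over the list alone; median 1.48, adjusted p = 6.71e-05, and 0.174 with an estimated correlation). SESN1 measured 2.74 ± 0.27, ZMAT3 at 2.69 ± 0.31 and SESN2 at 2.39 ± 0.41. TXNIP, an inhibitor of thioredoxin, rose in both lines at each time, by 1.49, 1.56 and 1.97 in BJ and 1.14, 1.45 and 1.46 in BJ LTSTERas.

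The effect at 24 h differed from that at 4 h for 2169 genes upward and 2083 downward in BJ and for 3045 and 1972 in BJ LTSTERas. In BJ SST (10.09 ± 0.24), CXCL8 (8.11 ± 0.75), ENPP5 (7.54 ± 0.10), CCL20 (7.16 ± 0.22) and DNER (7.06 ± 0.24) gained most. With untreated arrays as control CXCL8 gained 4.26 (adjusted p = 4.08e-08; range 2.94e-14 to 1.86e-04). KIF20A (-7.53 ± 0.78), CDC20 (-7.29 ± 0.71), PRRX1 (-7.28 ± 0.51), TNFRSF11B (-7.05 ± 0.24) and TRIM22 (-7.05 ± 0.45) lost most. In BJ LTSTERas DHRS2 (7.22 ± 0.24), CCL20 (7.20 ± 0.22), MIR7-3HG (6.07 ± 0.14), BEX5 (6.06 ± 0.20) and LINC02901 (5.77 ± 0.37) gained most. NRP1 (-8.52 ± 0.36), SERPINH1 (-7.85 ± 0.30), EMP1 (-7.70 ± 0.21) and PLAU (-7.36 ± 0.38) lost most. HMGA2 measured -6.66 and, with the mean of its probe sets, -0.44 (adjusted p = 0.265; range 2.19e-16 to 0.265). Of genes that rose at 4 h, 1313 of 1712 in BJ (521 expected with independence) and 1384 of 1824 in BJ LTSTERas (620 expected) had also risen at 24 h. Of those that fell, 1341 of 1844 in BJ (560 expected) and 1472 of 2266 in BJ LTSTERas (659 expected) had also fallen.

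How far the lines responded alike was read from the correlation of their effects across the 11412 genes, which are not independent replicates. Pearson's r was 0.770, 0.720 and 0.636 at 4, 12 and 24 h, and Spearman's rho 0.788, 0.750 and 0.676. At 24 h 2511 genes had risen in both lines (1179 expected with independence) and 2171 had fallen in both (1008 expected). Opposite calls with a called difference were found for 17, 158 and 406 genes, of which 10, 94 and 225 rose in BJ LTSTERas and fell in BJ. BIK at 24 h was called in BJ LTSTERas and not in BJ, and its difference passed. Across genes, the difference between the untreated lines had an r of 0.0961, 0.194 and 0.204 with the vorinostat effect in BJ and -0.117, -0.0974 and -0.0708 with that in BJ LTSTERas (rho 0.0318, 0.0961 and 0.124, and -0.162, -0.114 and -0.0725). Without BJ DMSO 4 h replicate 1 the first of these r was 0.0640.

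DMSO cultures were compared with untreated cells of the same line as a background for the drug. In BJ 24, 241 and 808 genes were higher and 75, 311 and 965 lower at 4, 12 and 24 h. In BJ LTSTERas 21, 27 and 320 were higher and 21, 27 and 431 lower. At 24 h in BJ the Wnt inhibitor APCDD1 (4.28 ± 0.43, adjusted p = 1.22e-08), the prostacyclin synthase PTGIS (4.04 ± 0.16) and SBF2-AS1 (3.82 ± 0.37) rose. CXCL8 (-5.67 ± 0.53, adjusted p = 3.06e-09), ESM1 (-4.51 ± 0.21), NPR3 (-4.41 ± 0.54) and EPHB1 (-4.32 ± 0.67) fell. PMAIP1 fell in BJ, with -1.21, -1.23 and -2.48 at the 3 times. In BJ LTSTERas at 24 h GPRC5B (2.58 ± 0.22, adjusted p = 2.26e-09) and GDPD1 (2.42 ± 0.25) rose and HAS2 (-3.22 ± 0.47), ALPK2 (-3.20 ± 0.36) and AMIGO2 (-2.31 ± 0.33) fell. Single arrays moved these counts by over 1.5 times. In BJ at 4 h, 10 were higher and 31 lower without DMSO replicate 3 and 48 lower without DMSO replicate 2. In BJ at 12 h, 110 were higher and 144 lower without untreated replicate 1, 153 higher without DMSO replicate 1, and 160 higher and 197 lower without DMSO replicate 2. In BJ LTSTERas at 4 h, 13 were higher without DMSO replicate 3 and 9 lower without untreated replicate 1. At 12 h in that line 15 were higher without untreated replicate 2, and 14 and 16 lower without untreated replicate 1 and DMSO replicate 2. At 24 h in that line 176 were higher and 219 lower without untreated replicate 1, 191 lower without DMSO replicate 2, 159 higher and 214 lower without DMSO replicate 3, and 877 lower without DMSO replicate 1. Fitted on only the groups compared, limma called 0 genes at 4 h in either line, where 962 in BJ and 558 in BJ LTSTERas had an unadjusted p under 0.05. It then called 1 higher and 2 lower in BJ and 3 and 1 in BJ LTSTERas at 12 h. At 24 h it called 482 and 564 in BJ and 23 and 34 in BJ LTSTERas. With the block by replicate number within a line the counts were 187 and 312, 897 and 1005, and 1695 and 1881 in BJ. They were 133 and 110, 113 and 156, and 1089 and 1412 in BJ LTSTERas.

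RNA quality was read from probe sets at the ends of ACTB and GAPDH. Over same-numbered arrays of a line and time, the 3' minus 5' signal of ACTB was lower with vorinostat than with DMSO in 7 of 9 pairs in BJ (mean -0.115) and in 9 of 9 in BJ LTSTERas (-0.229), and that of GAPDH higher in 7 of 9 in BJ (0.0394) and lower in 6 of 9 in BJ LTSTERas (-0.0308). Exact permutation adjusted p over pairs, run after the data were seen, were 0.0391, 0.0156, 0.0417 and 0.16. Same-numbered pairs are not independent. Per time, p was at least 0.2 (lowest possible 0.1). Over 20 leukocyte and endothelial markers the median in BJ at 24 h was -0.00342, where CD14 rose from 3.29 to 4.31 (adjusted p = 0.00124) and EGFL7 from 5.29 to 6.22 (adjusted p = 5.52e-04). Melanocyte markers rose for 2 of 3 in each line at 24 h (median 3.43 in BJ and 2.17 in BJ LTSTERas, adjusted p = 0.108 and 0.15). In BJ that list was called with untreated arrays as control (0.0484) and without the 7 BJ replicate 1 arrays (0.0489), in a range of 0.0484 to 0.198.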

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

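Of the tests in this part, those of chemokine drift, of IL6 and CXCL1 drift, of a change of total mRNA large enough to make the whole mitosis difference, of p53 targets under log2 10 and of drift as the whole cause of the p53 difference were chosen only after the results were seen, and the fit without the 7 BJ replicate 1 arrays was added after the data were seen. What brought each result here was a passed test of the difference between lines or between times.

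The first pattern weighed is the fall of mitosis genes, which was deeper in BJ than in BJ LTSTERas at 24 h by a median of 3.54 (adjusted p = 1.52e-13, and 0.608 with an estimated correlation). Drift of the BJ DMSO cultures is argued against, as the 30 genes had a median of -4.50 ± 0.313 against untreated BJ arrays. So is an effect of the 7 BJ replicate 1 arrays, as the median difference was 3.45 ± 0.334 without them. A change of total mRNA hidden by the normalization cannot be told apart. The 12 poly-A control probe sets differed between lines by 0.763 ± 0.387, which spans the predicted size of 1. Added to RNA, they cannot show a change per cell. As the whole cause, a change per unit RNA is argued against, since the mitosis difference less that of the controls was 2.77 ± 0.516. A line difference in the response of cell division to vorinostat stays a candidate, untested here, as does one in its rate before treatment.

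The second pattern is the rise in BJ and not in BJ LTSTERas at 24 h, against DMSO and with a passed difference, of 6 members of the secretory list. For all 6, drift of the BJ DMSO control cannot be told apart. Their median against untreated BJ arrays, 2.00 ± 0.578, joins 4 that rose past the threshold and 2 that did not. CXCL8, CXCL2, CXCL3 and CCL7 were picked by their rise against untreated arrays (lowest 1.92 ± 0.531), so that rise is no separate test. CXCL8 rose by 7.75 against DMSO and 2.08 against untreated arrays. IL6 and CXCL1 were picked as the 2 that did not rise there (higher -0.18), so drift cannot be told apart. Leukocytes or endothelial cells in BJ cultures are argued against. The median of 20 markers was -0.00342 ± 0.0793. Yet CD14 (1.02, adjusted p = 0.00124) and EGFL7 (0.93, adjusted p = 5.52e-04) rose. A line difference in the control of these chemokines may remain, and was not tested further.

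The third pattern is the difference of p53 targets between the lines, with a median of 1.48 at 24 h (adjusted p = 6.71e-05, and 0.174 with an estimated correlation). The list had a median of -0.91 in BJ and of 0.08 in BJ LTSTERas (adjusted p = 0.392), where CDKN1A rose by 3.20. Choice of probe set is argued against, as the mean of probe sets gave a median difference of 1.65 ± 0.266. A signal ceiling is argued against for the 13 targets with a BJ DMSO mean under log2 10. Their BJ median was -1.15 ± 0.276. For CDKN1A itself, at log2 11.76, a ceiling cannot be told apart, because 2.99% of genes at that level, 17 of 569, rose by at least 1, between the predicted bounds. Drift of the DMSO controls, as the whole cause or a part, cannot be told apart. Against untreated arrays the median difference was 1.07 ± 0.263, with a list call (adjusted p = 0.0023, the highest over alternatives). For a part, 1.07 lay within its error of the bound of 1, and for the whole that error may be too small. A line difference in p53 output may remain beside it.

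Counts of genes with a passed difference between lines were 259 higher and 242 lower at 4 h, 1562 and 1175 at 12 h, and 2630 and 2008 at 24 h. From 4 h to 24 h the effect differed upward for 2169 genes and downward for 2083 in BJ, and for 3045 and 1972 in BJ LTSTERas.

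Each comparison was also fitted on its own arrays, or on the differences of same-numbered arrays where 4 groups enter, for all 10 splits of the 6 values. Splits that number 10 are too few for a share under 0.05. The real split called 3028, 5430 and 6882 genes for vorinostat in BJ at 4, 12 and 24 h and 3195, 5973 and 6582 in BJ LTSTERas. It called 825, 4272 and 5750 for the difference between lines, 5269 for the untreated lines, and 5879 and 5927 for the change from 4 h to 24 h in BJ and BJ LTSTERas. For DMSO against untreated cells it called 0, 3 and 1046 in BJ and 0, 4 and 57 in BJ LTSTERas, with 962 and 558 genes at an unadjusted p under 0.05 in limma where it called 0. In each comparison the highest of the other splits was 0. In the 12 comparisons of 2 groups of a line, 3 of these part every same-numbered pair. So 1 of 10 splits gave as many genes as the real one, and 10 of 10 for both DMSO comparisons at 4 h.

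Lists whose difference between lines passed at 4 h had medians of 0.55 for p53 targets, -0.35 for RAS-MAPK output and feedback, 0.37 for interferon-stimulated genes, 0.28 for antigen presentation and -0.34 for ribosome biogenesis, with adjusted p of 0.303, 0.678, 0.678, 0.608 and 0.608 with an estimated correlation. Leaving out single arrays ended 3 of these calls. RAS-MAPK (range 0.00535 to 0.312 over the alternatives) ended without BJ vorinostat replicate 1 (0.238), BJ DMSO replicate 3 (0.0856), BJ LTSTERas vorinostat replicate 3 (0.0982) or DMSO replicate 2 (0.125), without the 7 BJ replicate 1 arrays (0.122), and with untreated arrays as control (0.312), where it turned upward (median 0.14). Interferon genes (0.00267 to 0.183) ended without BJ vorinostat replicate 1 (0.119), BJ DMSO replicate 3 (0.183), BJ LTSTERas vorinostat replicate 1 (0.0745) or DMSO replicate 3 (0.162), and with the stricter floor (0.126). Antigen presentation (0.00179 to 0.0694) ended without BJ vorinostat replicate 1 (0.0694) or BJ LTSTERas vorinostat replicate 2 (0.0588).

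At 12 h the medians were 0.64 for caspases and apoptosome, 0.66 for G1/S cyclins and E2F targets, 0.45 for replication, 1.16 for mitosis, 1.08 for p53 targets, -0.78 for metallothioneins, -0.73 for RAS-MAPK, -0.49 for matrix proteases, and -0.38 for ribosome biogenesis. Neuronal and synaptic genes had a median of 0.0156 and a mean of -1.05, and camera called them lower in BJ LTSTERas. With an estimated correlation the adjusted p were 0.608, 0.678, 0.699, 0.719, 0.116, 0.608, 0.608, 0.608, 0.608 and, for neuronal genes, 0.0542. Mitosis had 5 passed members of 30 and 0 by limma when adjusted over the list alone, and with untreated arrays as control its adjusted p was 0.846 (range 1.93e-07 to 0.846). With that control the calls of RAS-MAPK (0.701, range 0.00593 to 0.701), which camera then placed upward, replication (0.2), G1/S cyclins (0.122) and matrix proteases (0.0891) ended too. Caspases (range 0.00139 to 0.0987) ended without BJ vorinostat replicate 1 (0.0987), BJ DMSO replicate 2 (0.0598), BJ LTSTERas vorinostat replicate 3 (0.0583) or BJ LTSTERas DMSO replicate 2 (0.0603) or 3 (0.0574), and under 8 other alternatives. G1/S cyclins (8.94e-04 to 0.132) ended without BJ vorinostat replicate 1 (0.122), BJ DMSO replicate 2 (0.0808) or BJ LTSTERas DMSO replicate 3 (0.0608), and under 3 more alternatives, up to 0.132 with the mean of probe sets. Replication (7e-05 to 0.2) ended without BJ vorinostat replicate 1 (0.0823) or BJ DMSO replicate 2 (0.0615), and matrix proteases (0.00702 to 0.0891) without BJ vorinostat replicate 1 (0.0595) or BJ LTSTERas DMSO replicate 2 (0.0543) or the second-scan arrays (0.0843).

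At 24 h the medians were 1.38 for pro-apoptotic BCL2 family genes (1.12 and adjusted p = 0.0503 without BJ vorinostat replicate 1, range 6.07e-04 to 0.0503), 0.93 for caspases and apoptosome, 0.83 for G1/S cyclins and E2F targets, 1.12 for replication, 3.54 for mitosis and 1.48 for p53 targets. They were -1.39 for metallothioneins, -1.15 for RAS-MAPK, -1.05 for the secretory list, -0.88 for extracellular matrix, -0.83 for matrix proteases and -1.20 for neuronal genes. With an estimated correlation the adjusted p were 0.471, 0.608, 0.608, 0.608, 0.608 and 0.174 for the first 6 lists and 0.354, 0.608, 0.608, 0.678, 0.608 and, for neuronal genes, 0.0393 for the others. With untreated arrays as control the calls of RAS-MAPK (0.544, range 5.3e-05 to 0.544), the secretory list (0.113, range 1.55e-04 to 0.113) and matrix proteases (0.0556, range 4.71e-04 to 0.0556) ended. That of extracellular matrix ended with the mean of probe sets (0.132, range 2.4e-05 to 0.132).

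Among genes, the differences at 4 h were 4.77 for PHETA2, 4.70 for PCDH10, 4.54 for ST8SIA4, 4.54 for SALL1 and 4.49 for KCNJ2, and -5.25 for ADAMTS15, -4.02 for DUSP2, -3.84 for INA, -3.72 for CXCL3 and -3.68 for CXCL2. At 12 h they were 7.28 for LHX9, 6.67 for MKX, 6.36 for IRAG1, 6.19 for EFS and 5.90 for DIO2, and -8.01 for SST, -6.86 for CXCL8, -5.90 for INA, -5.82 for ENPP5 and -5.80 for DOCK4. At 24 h they were 7.88 for DIO2, 7.38 for SLC38A11, 7.35 for TRIM22, 7.35 for LHX9 and 7.27 for IRAG1, and -9.97 for CXCL8, -9.75 for SST, -7.55 for ENPP5, -7.27 for IL6 and -7.24 for CXCL2.

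In the apoptosis lists the 12 h differences were 0.80 for BCL2L11, 1.23 for BIK, 0.87 for BAK1, 0.70 for BNIP3 and -0.97 for BCL2A1, and the 24 h differences 1.67 for BCL2L11, 2.25 for BAD, 3.95 for BIK, 1.09 for BAK1, 1.84 for BNIP3, 1.23 for BCL2L1 and -4.69 for BCL2A1. Of the caspase and apoptosome list, ENDOG (1.86), APAF1 (1.33), HTRA2 (1.29) and DIABLO (1.21) passed at 24 h. BNIP3 at 12 h ended without BJ vorinostat replicate 1 (0.0575), 2 (0.0657) or 3 (0.0535), BJ DMSO replicate 1 (0.0837) or 3 (0.0612), BJ LTSTERas vorinostat replicate 2 (0.0692) or 3 (0.0962), and BJ LTSTERas DMSO replicate 1 (0.0577), 2 (0.0611) or 3 (0.0597). BCL2L1 at 24 h ended without BJ vorinostat replicate 1 (0.0548), BJ DMSO replicate 2 (0.0537) or 3 (0.0655), BJ LTSTERas vorinostat replicate 2 (0.0636) or BJ LTSTERas DMSO replicate 3 (0.0911), and was 1.06 (adjusted p = 0.347) with the mean of its probe sets.

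Of the p53 targets CDKN1A (2.94), SESN1 (2.33), ZMAT3 (2.19) and SESN2 (1.90) passed at 12 h, and CDKN1A (3.52), SESN1 (2.74), ZMAT3 (2.69) and SESN2 (2.39) at 24 h. At 24 h the mitosis genes KIF20A (7.01), KIF2C (6.97), DLGAP5 (6.96) and CDC20 (6.94) and the replication genes MCM10 (4.67), RFC3 (4.00), CDC45 (3.91) and ORC6 (3.51) passed. So did the metallothioneins MT1M (-6.14), MT1G (-1.98), MT1H (-1.43) and MT1E (-1.41), the neuronal genes INA (-6.83), NEFH (-5.96), SCG2 (-4.95) and NEFM (-4.03), and CXCL3 (-7.08). The RAS-MAPK genes EMP1 (-4.76), PHLDA1 (-3.88), CCND1 (-3.63) and ETV1 (-3.20) and the matrix genes LUM (4.20), LOX (-3.23), COL6A3 (-2.88) and FBN1 (-2.84) passed as well.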

How the results depend on the processing

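Of the alternatives here, the block by replicate number within each line, the list correlation estimated under it, and the fit without the 7 BJ replicate 1 arrays were chosen only after the data were seen, and the other tests before. Of 762 counts of called genes under an alternative, 657 lay within 1.5 times the reported count and 105 did not. Of 10626 values of named genes past the threshold, 10338 kept direction and call, 285 kept direction and lost the call, and 3 reversed. Of 4845 values not past it, 172 gained a call. Of these, 46 did so under the within-line block. For vorinostat they were in BJ BAX at 4 h, BAK1, BNIP3, BNIP3L, BOK and HRAS at 12 h, and CDKN1A, HRAS and MCL1 at 24 h, and in BJ LTSTERas BAK1, BNIP3 and BNIP3L at 4 h, BAX and HRAS at 12 h, and BAX, HRAS and MCL1 at 24 h. For the difference between lines they were BCL2L11, CDKN1A and MCL1 at 4 h, BAD, BAX, BCL2L2 and HRAS at 12 h, and BAX, BNIP3L, BOK and HRAS at 24 h. From 4 h to 24 h they were BAX, BCL2L2, CDKN1A and HRAS in BJ and BAD and HRAS in BJ LTSTERas, and the other 12 were for DMSO. HRAS at 24 h measured -0.88 in BJ and 0.51 in BJ LTSTERas, with a difference of 1.39 (adjusted p = 0.103, 0.364 and 0.0929, and 3.77e-05, 0.0089 and 1.69e-05 under this block, each the lowest of ranges up to 0.5, 0.849 and 0.291). Of 7952 list tests, 7414 were on the reported side of the threshold, 240 lost a call, 296 gained one and 2 reversed. The estimated correlation alone ended 63 list calls, 56 under the within-line block, which gives no value for the untreated lines, and fry ended 4 and gained 175, where fry compares a list with no other genes. Signal over background limits genes below the floor, and a change that starts or ends at background has no measured size beyond it.

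With a 2-fold minimum, which by construction calls fewer genes, higher and lower counts for vorinostat were 707 and 685, 1446 and 1554, and 1783 and 1947 in BJ at 4, 12 and 24 h, and 854 and 802, 1808 and 1474, and 2184 and 1887 in BJ LTSTERas. For the difference between lines they were 155 lower at 4 h, 866 and 654 at 12 h, and 1530 and 1263 at 24 h, for the untreated lines 1258 and 1513, and for 4 h to 24 h 1145 and 1329 in BJ and 1687 higher in BJ LTSTERas. For DMSO they were 9 and 35, 93 and 119, and 261 and 335 in BJ, and in BJ LTSTERas 13 higher at 4 h, 14 lower at 12 h, and 107 and 89 at 24 h.

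For the counts below, the cause was not tested. Array weights gave 469 higher and 520 lower for the 4 h difference, and for DMSO in BJ 344 and 531, 1262 and 1501, and 2071 and 2262. The block by replicate number gave 430 and 469 for the 4 h difference, for DMSO in BJ 86 and 162, 500 and 584, and 1239 higher at 24 h, and in BJ LTSTERas 58 and 46, 54 and 67, and 702 and 884. The block within each line gave 628 and 767 for the 4 h difference and 2789 and 2059 for that at 12 h, for DMSO in BJ 187 and 312, 897 and 1005, and 1695 and 1881, and in BJ LTSTERas 133 and 110, 113 and 156, and 1089 and 1412. A fit of only the groups compared gave 161 lower for the 4 h difference. For DMSO in BJ it gave 0 and 0, 1 and 2, and 482 and 564, and in BJ LTSTERas 0 and 0, 3 and 1, and 23 and 34, where limma's 0 at 4 h stand beside 962 and 558 genes at an unadjusted p under 0.05. Untreated arrays as control gave 396 higher for the 4 h difference. For DMSO at 12 h, the stricter floor gave 17 lower in BJ LTSTERas, the fit without the second-scan arrays 16 higher there, and the fit without the 7 BJ replicate 1 arrays 136 higher in BJ.

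Leaving out each array in turn, with 2 arrays left in its group, DMSO counts ran from 10 to 25 higher and 31 to 95 lower in BJ at 4 h, from 110 to 311 and 144 to 371 at 12 h, and in BJ LTSTERas from 13 to 23 and 9 to 24 at 4 h, 15 to 28 and 14 to 24 at 12 h, and 159 to 450 and 191 to 877 at 24 h. The r of the BJ effect at 4 h with the untreated difference ran from 0.0640 to 0.128. With untreated arrays as control that r was 0.135, and the r between lines was 0.748 at 4 h and 0.663 at 24 h. The cause was not tested for these.

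Results that reversed included the RAS-MAPK difference between lines with untreated arrays as control, which camera then placed upward, with a median of 0.14 at 4 h and of -0.084 at 12 h, where the median kept its sign. The others were PMAIP1 in BJ, -0.80 at 12 h and -0.68 at 24 h with that control, and IDI1 in BJ LTSTERas at 4 h, -0.093 without _x_at probe sets. PMAIP1 was lower in BJ DMSO than in untreated cultures, with differences of -1.23 and -2.48 at those times, which the change of control brings in. IDI1 was then read from another probe set, and for RAS-MAPK the cause was not tested.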

Other observations

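The gene lists and comparisons in this part were fixed before the data were examined, that of the poly-A controls was set afterwards, and which lists to describe was chosen after their values were seen. Histone deacetylase and sirtuin genes, a list that holds the drug's targets, rose for 10 of 18 and fell for 2 in BJ LTSTERas at 24 h (median 0.71, adjusted p = 0.0818, and 0.0193 with no filter, in a range of 0.0193 to 0.126) and rose for 8 and fell for 3 in BJ (median 0.40, adjusted p = 0.328). HDAC3 rose by 2.32 ± 0.15 in BJ and 1.78 ± 0.15 in BJ LTSTERas. HDAC11 rose by 2.63 ± 0.36 in BJ LTSTERas and measured 0.65 in BJ (adjusted p = 0.123), with a difference of 1.98 (adjusted p = 0.00232). SIRT1 fell in BJ (-1.44 ± 0.19) and measured 0.01 in BJ LTSTERas, with a difference of 1.45 (adjusted p = 4e-05). Heat shock genes fell for 9 of 15 in each line and rose for 3 in BJ and 2 in BJ LTSTERas (adjusted p = 0.446 and 0.126, the latter 0.00941 with no filter, in a range of 0.00941 to 0.311).

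Interferon-stimulated genes fell for 8 of 16 and rose for 4 in BJ at 24 h (adjusted p = 0.192) and fell for 7 and rose for 5 in BJ LTSTERas (adjusted p = 0.747). XAF1 fell in BJ (-4.63 ± 0.34) and measured -0.44 in BJ LTSTERas (adjusted p = 0.269), where both group means lay under log2 4, with a difference of 4.19 ± 0.48 (adjusted p = 2.01e-08).

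Between the untreated lines, histone genes were lower in BJ LTSTERas for 7 of 10 and higher for 1 (median -1.26, adjusted p = 0.00928, and 0.454 with an estimated correlation). Metallothioneins were lower for 6 of 8 and higher for 0 (median -0.78, adjusted p = 0.0211, and 0.454 with an estimated correlation). Cytoplasmic ribosomal protein genes were higher for 13 of 20 and lower for 0 (median 0.28, adjusted p = 0.0148, and 0.541 with an estimated correlation). General transcription and splicing genes were higher for 11 of 19 and lower for 1 (median 0.47, adjusted p = 0.0211, and 0.238 with an estimated correlation).

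Fibroblast markers fell for 8 of 14 and rose for 2 in each line (adjusted p = 0.0554 and 0.0965). With no filter both were called, each at 0.00737. In BJ they were also called with the mean of probe sets (0.026), a fit of only the groups compared (0.0292), a second quantile normalization (0.0373), centred arrays (0.0493), the block within a line (0.0499) and without BJ vorinostat 24 h replicate 3 (0.0485). The ranges were 0.00737 to 0.196 in BJ and to 0.255 in BJ LTSTERas. Of the germline list 0 genes passed the signal floor, and of the leukocyte list 1 did.

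The 12 probe sets of the added poly-A controls differed between vorinostat and DMSO at 24 h by -0.21 in BJ and 0.55 in BJ LTSTERas (SE 0.27).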
